A study of Homo sapiens with 4 samples.

How the data were processed

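Small RNA of AGS cells, a human gastric adenocarcinoma epithelial line, was measured on 4 single-colour Agilent human miRNA arrays, 2 from uninfected cells and 2 from cells kept with Helicobacter pylori at a multiplicity of infection (bacteria added per cell) of 100 for 4 h. Per the labels' protocols, total RNA was extracted with a kit that retains small RNA, and the dye Cy3 was ligated to RNA 3' ends before hybridization. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

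The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers; the processed signal is the background-subtracted and spatially detrended intensity of a spot and was not normalized between arrays. Each array had 53880 miRNA spots for 3523 probes, 10 to 40 spots per probe and 1 to 4 probes per miRNA. The probes covered 1347 miRNAs, of which 1205 were human and 142 were viral. The authors also deposited 1 table of log2 values for the same arrays. Set against the scanner files, its values equalled the log2 of the total signal per miRNA, with values under 1 raised to 1, plus 1 constant per array, centred on the median of each miRNA; the largest deviation was 1.8e-06. Its column medians were 0.10 and -0.20 for the uninfected arrays and 0.17 and -0.10 for the infected arrays, and 994 of its 1347 miRNAs stood at the floor on all arrays. Its scale and direction were thus settled from the values, while the software that made it is not given in the sources used here. It served as an alternative.

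Control spots and spots with an outlier flag were left out (4.36% to 5.43% of miRNA spots per array), and no kept miRNA spot was saturated. The remaining spots of a probe were averaged. A probe counted as detected on an array when at least 50% of its kept spots were well above background by the scanner's flag. Because 13.1% to 15.4% of probes were detected per array, each array was divided by its 75th percentile over the 440 probes detected on all 4 arrays. A common floor was then set at the median over arrays of the 5th percentile of the scaled signal of detected probes (0.0534, or -4.23 on the log2 scale), and log2 was taken. A miRNA was represented by its probe with the highest mean over the 4 arrays. A miRNA was tested if any of its probes was detected on at least 2 of the 4 arrays, which left 304 (286 human and 18 viral).

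Differences, infected minus uninfected, were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with files read by the data.table package (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method over the tested miRNAs with a threshold of 0.05. The moderated fit had 3.28 degrees of freedom. Where no probe of a miRNA was detected on any array of a group, the fold is given as a lower bound, computed from the mean of normalized log2 values of the brighter group against the mean, per array, of the floor or the dim probe's own value if higher. A value at the floor has no spread of its own, so the SD of a group with both arrays at the floor is 0 by construction. The SE and p of such a miRNA do not measure the spread in that group. The 15 lists of miRNAs were fixed before the data were examined. The 13 with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation. Adjustment was over the lists. The estimated version takes its degrees of freedom from the 4 arrays rather than from the number of miRNAs, so it has little power here. The lists, named by their content, are given with their results in the report. Members of a list were also adjusted over the list alone.

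The miRNAs named were chosen by a rule fixed before the data were examined. Per direction it took up to 12 human miRNAs with non-overlapping groups: those that passed, filled to 6 with the lowest p of that direction. It also took the 3 members with the lowest p of each list, and in any case miR-155-5p, miR-146a-5p, miR-21-5p, miR-372 and miR-373-3p. Any other miRNA is said to be chosen after its values were seen.

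The test was checked on simulated values for the 304 tested miRNAs in the same 2 against 2 design, with 60 changed in each of 20 runs. For the comparison of infected with uninfected cells it recovered 34% of changes of 0.5 on the log2 scale, 72.2% of changes of 1 and 94% of changes of 2. It made 1.5 false calls per run on average. The runs made 41.55 calls on average, against 4 in the data, and more calls loosen the adjusted threshold. These shares may thus overstate the recovery possible here. The number of arrays limits the precision. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333, so no such test was run for single values.

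All 4 arrays lay on 1 slide and were scanned together. The groups lay at different positions of the slide, 1 and 3 on its second index, so this position and group cannot be told apart. On the first index, equally numbered arrays of the groups shared a position, 1 or 2. Alternatives covered the scaling, the background correction, the signal column, the deposited table, the summary of probes, the floor, the filter on dim probes, the replicate number as a block, the trend option of eBayes and leaving out each array in turn. The file header names the human genome build hg19, while the gene table used here is of GRCh38.p14; that table was used only to say which miRNA genes lie within or beside other genes, without regard to strand, which it does not give, and no coordinates are printed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.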

Results

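Expression of miRNAs was compared between uninfected AGS cells and AGS cells kept with H. pylori for 4 h, with 2 arrays per group. The study's question was which miRNAs of a gastric epithelial line are altered by the bacterium. The 75th percentile of detected probes, a measure of array brightness, was 424 and 510 intensity units on the uninfected arrays and 362 and 413 on the infected arrays. The uninfected arrays detected 262 and 281 miRNAs and the infected arrays 296 and 302, that is 271.5 ± 13.4 against 299 ± 4.24 (mean ± SD, n = 2), a difference of 27.5. Across the 304 tested miRNAs, log2 signals correlated at r = 0.993 between the uninfected arrays and 0.990 between the infected arrays, and at 0.964 to 0.976 between arrays of different groups; miRNAs are not independent replicates, so no p is attached.

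In infected against uninfected cells, 4 miRNAs differed past the threshold: signal rose for miR-671-5p, miR-670 and miR-4257 and fell for miR-93-5p. The groups lay at different positions of the slide, so slide position and group cannot be told apart. miR-671-5p, known for directing cleavage of the circular RNA of the CDR1 locus, stood at 0.38 ± 0.25 (log2 relative to the 75th percentile, SD, n = 2) in infected cells. Its brightest probe was not well above background on either uninfected array and was set to the floor of -4.23 there. The fitted log2 change was 4.60 (SE 0.15, limma adjusted p = 0.0125), a size that depends on the floor. With both uninfected values at the floor, the SE and p do not measure the uninfected spread. Before scaling, the intensity was 11.4 and 17.1 on the uninfected arrays and 415 and 606 on the infected arrays. A second probe, detected on 1 of the 2 uninfected arrays, gave a log2 change of 4.17, also against a value at the floor on the other.

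miR-670 was not well above background on either uninfected array and was at least 4.88-fold higher in infected cells (fitted log2 change 2.29, SE 0.15, limma adjusted p = 0.0300). Its uninfected values were also both at the floor, so the same limit holds for its SE and p. Its second probe, not well above background on the uninfected arrays either, gave a log2 change of at least 1.99. miR-4257, a dim signal in both groups, rose by 1.40 (SE 0.07, limma adjusted p = 0.0261), or 2.64-fold, but its probes disagreed in size, with 1.40 for the brighter and 0.21 for the other. The uninfected values of that other probe were set to the floor, which limits the 0.21. Before scaling it gave 18.6 and 23.8 on the uninfected arrays and 22.1 and 25.9 on the infected arrays. miR-93-5p, a member of the miR-17 seed family that represses the cell cycle inhibitor CDKN1A, fell by 1.35 (SE 0.09, limma adjusted p = 0.0300). It was 2.55-fold lower, at 0.40 ± 0.09 in uninfected and -0.95 ± 0.02 in infected cells (SD, n = 2), and its second probe gave -0.94. In the gene table, MIR671 lies within CHPF2, MIR670 within HSD17B12, MIR4257 within ADAMTSL4, and MIR93 within MCM7, where MIR106B and MIR25 are its nearest miRNA neighbours.

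**Figure D1:**
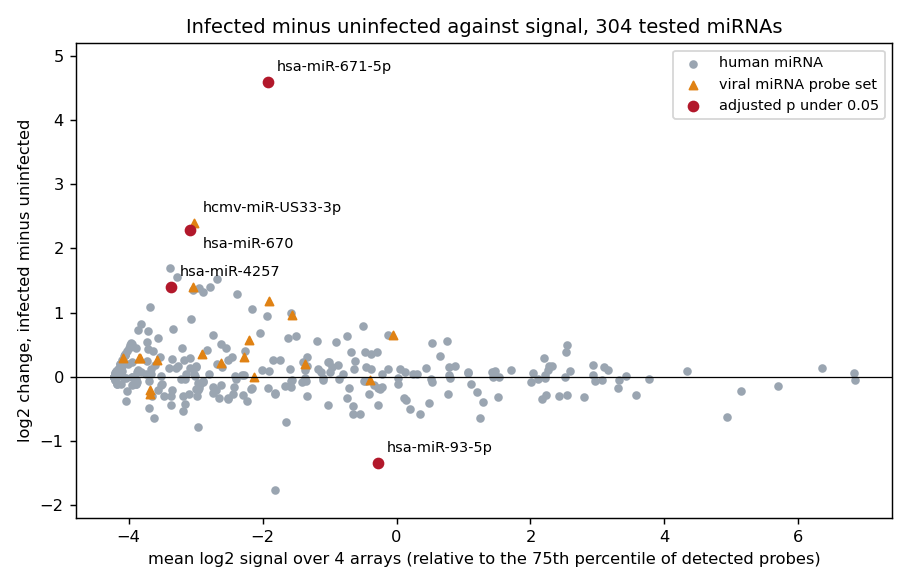
Log2 change (infected minus uninfected) against mean log2 signal over the 4 arrays for the 304 tested miRNAs; grey points are human and orange triangles viral miRNAs, and red points passed the adjusted threshold. The changes over 1 lie among dim signals, and those of miR-671-5p (4.60), miR-670 (2.29) and hcmv-miR-US33-3p (2.39) rest on uninfected values at the floor, so they have no order, while miR-93-5p (-1.35) is the one call below 0.

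The next miRNAs by p did not pass in the main setting. On the higher side, miR-1180 gave 1.55 with an adjusted p of 0.0648 from limma, with 1 of its 2 uninfected values at the floor, and its second probe stayed at the floor on all arrays. miR-3131 and miR-2117, not well above background in uninfected cells, were at least 2.11-fold and 1.66-fold higher, each with an adjusted p of 0.0648. On the lower side, miR-361-5p, whose gene lies within CHM, gave -1.76 (SE 0.23, limma adjusted p = 0.0695). miR-19b-1-5p, a minor arm from the MIR17HG transcript, gave -0.79 (adjusted p = 0.0658), on 1 of its 4 probes. miR-4284 gave -0.63, miR-135b-5p -0.46 and miR-302b-3p, a stem cell miRNA, -0.59, with adjusted p-values of 0.0815 to 0.117. In each of these the infected values lay on one side of both uninfected values, which the naming rule required, so this adds no support.

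Over all 304 tested miRNAs, 52 had an unadjusted p under 0.05 on the higher side and 18 on the lower side. That balance turned to 32 and 53 with the percentile over all probes, 34 and 39 with quantile normalization and 42 and 48 in the deposited table, and was 37 and 27 with median scaling. The filter let in 20 human and 2 viral miRNAs detected on both infected and no uninfected arrays, against 2 the other way. That favours the higher side. Among the 254 miRNAs detected on all 4 arrays the balance was 33 and 18. The calls numbered 3 higher and 1 lower, against 3 higher and 2 lower with quantile normalization. The share of miRNAs with a change above 0 was 57.9%, against 44.7% with quantile or median scaling, 30.9% when the percentile was taken over all probes, and 32.2% in the deposited table, since these last 2 moved the median change by -0.18. Among miRNAs detected on all 4 arrays that share was 52.8%. The 4 calls were lost without uninfected replicate 1, infected replicate 1 or infected replicate 2, when 0 miRNAs passed in limma (18 to 29 higher and 7 to 12 lower at an unadjusted p under 0.05), and the count rose to 13 higher and 2 lower without uninfected replicate 2; with a floor 4 times lower it was 31 higher and 3 lower. miR-670 and miR-4257 also did not pass after normexp background correction, nor miR-93-5p when its probes were averaged.

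**Figure D2:**
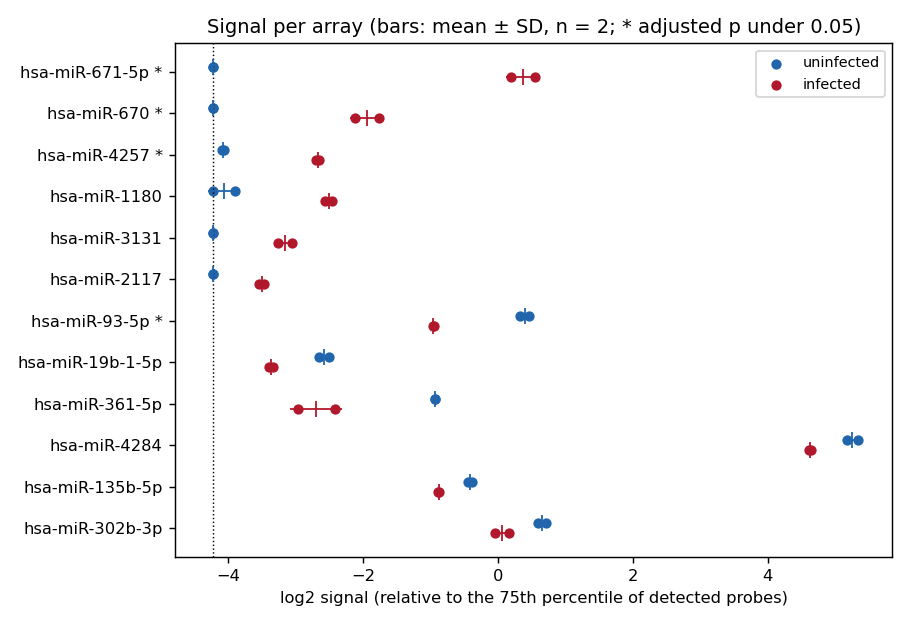
Log2 signal relative to the 75th percentile of detected probes on each array for the 12 miRNAs named by rank; points are arrays (blue uninfected, red infected), ticks and bars give mean ± SD (n = 2), the dotted line is the floor, and asterisks mark adjusted p under 0.05. Uninfected values of miR-671-5p, miR-670, miR-3131 and miR-2117 lie at the floor of -4.23, as does 1 of the 2 of miR-1180. The groups do not overlap for any of the 12, because the naming rule required it.

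The miR-17-92 cluster and its paralogs, a family of proliferation-associated miRNAs, was the list that shifted. Of its 14 tested members 12 had a change below 0, with a median of -0.30, and the list was lower relative to other miRNAs (camera adjusted p = 0.000392). The call was lost with an estimated correlation (camera adjusted p = 0.600). That estimate was -0.037, below the preset 0.01, so the loss does not show correlation among members. That version has few degrees of freedom and could hardly pass. The call was also lost with quantile normalization (median -0.23, camera adjusted p = 0.10, the highest over the alternatives). The lowest was 5.72e-10 with no filter, where the median was 0. Over all miRNAs 1 member fell, miR-93-5p, and adjusted over the list alone 2 fell, miR-93-5p and miR-19b-1-5p. miR-18a-5p gave -0.37 (limma adjusted p = 0.177). The cluster neighbours of miR-93-5p, chosen after their values were seen, gave -0.03 for miR-106b-5p (SE 0.10) and 0.02 for miR-25-3p (SE 0.08).

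Inflammation and NF-kB responsive miRNAs were mostly not measured: 6 of 23 arms on the array were tested. miR-155-5p and miR-146a-5p, which NF-kB induces in many cells, were not detected on any array. miR-21-5p gave 0.06 (SE 0.19), a value that turned to -0.16 with the percentile over all probes, -0.15 in the deposited table and -0.02 with median scaling. Its other arm miR-21-3p gave 0.14, or -0.08 with the percentile over all probes and -0.03 in the deposited table, and miR-212-3p gave -0.30. Adjusted over the list alone 1 member rose, miR-31-3p, by 0.79 (SE 0.09), with an adjusted p of 0.0658 over all miRNAs by limma. The list as a whole did not shift (camera adjusted p = 0.709).

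The miRNAs on the list of those linked to H. pylori infection went both ways, 4 of 11 above 0 and 7 below (camera adjusted p = 0.675). Adjusted over the list alone 1 rose, the hypoxia-responsive miR-210, by 0.99 (SE 0.14, limma adjusted p = 0.0788 over all miRNAs), and both of its probes moved alike. miR-30b-3p was not well above background on the infected arrays, at least 1.30-fold lower (limma adjusted p = 0.140), and miR-200b-5p gave 0.26, or -0.04 in the deposited table. In the miR-30 family, 6 of 6 members were below 0 with a median of -0.15 (camera adjusted p = 0.131), among them miR-30b-5p at -0.64 and miR-30c-5p at -0.18, and none passed over the list alone by limma, with 1 at an unadjusted p under 0.05. The stem cell cluster of miR-371, miR-372 and miR-373 had 5 of 5 members below 0 (median -0.15, camera adjusted p = 0.356), and none passed over the list alone or had an unadjusted limma p under 0.05. miR-372 gave -0.06 (SE 0.14), miR-373-3p -0.15, miR-373-5p -0.34 and miR-371a-3p -0.23, the last turning to 0.10 with quantile normalization. In the same order, their second probes gave -0.21, -0.76, 0 (at the floor) and 0.02.

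Epithelial and growth-related families showed no shift. The let-7 family had a median of 0.07 over 9 members (camera adjusted p = 0.980), with let-7b-5p at 0.29, let-7g-5p at 0.17 and miR-98-5p at 0.16, and its median turned to -0.15 with the percentile over all probes, -0.14 in the deposited table and -0.01 with median scaling. The miR-200 family, which keeps cells epithelial, had a median of -0.03 over 8 members (camera adjusted p = 0.971), with miR-141-3p at -0.18 and miR-200a-5p at 0.19. The clusters of miR-221, miR-222, miR-23, miR-27 and miR-24 had 6 of 10 members above 0 (camera adjusted p = 0.675), with miR-23b-3p at -0.32 and miR-27b-3p at -0.30 by contrast, and miR-23a-5p, not well above background in uninfected cells, was at least 1.14-fold higher. The miR-34 and p53 responsive list had 6 of 9 above 0 (camera adjusted p = 0.709), with miR-215 at -0.42, miR-34a-3p at -0.10 and miR-103a-3p at 0.09. The medians of these last 2 lists, 0.03 and 0.04, were below 0 in the deposited table and with the 3 other scalings. For both, the mean (-0.01 and -0.0041) and the camera direction were below 0, unlike the median, and in the miR-200 family the mean (0.02) was above 0. Of these 4 lists no member passed over the list alone by limma, and 3 had an unadjusted p under 0.05.

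Among the miRNAs of gastrointestinal epithelium, 8 of 12 were above 0. The median was 0.11, or -0.11 with the percentile over all probes and -0.12 in the deposited table, and the camera test pointed downward (adjusted p = 0.980), so the signs differed. Adjusted over the list alone 1 rose, miR-29b-1-5p, by 1.40 (SE 0.19, limma adjusted p = 0.0746 over all miRNAs). Its partner arm miR-29b-3p, whose family represses collagen genes, gave 0.50 (SE 0.14), but its second probe gave 0.04. This list shares 4 tested members with the p53 responsive one, among them miR-215.

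Markers of other cell types were few. Of the haematopoietic arms 4 of 16 were tested, with a median of 0.01 that lay below 0 in the deposited table and with the 3 other scalings (mean -0.00055, camera upward, adjusted p = 0.980), and miR-150-3p gave 0.29, miR-181a-3p -0.30 and miR-142-3p 0.03. No muscle, stroma or endothelium arm of 19 was detected on enough arrays to be tested. Of the liver and neuron arms 2 of 14 were tested, miR-128 at 0.31 and miR-138-2-3p at -0.27, too few for a list test.

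Signals that vary with RNA quality on such arrays, from G-rich probes, had 16 of 23 members above 0 with a median of 0.25 (camera adjusted p = 0.25). miR-765 gave 1.52 (SE 0.18, limma adjusted p = 0.0658), miR-638 0.39 and miR-3162-5p 0.53; no member passed over the list alone by limma, and 7 had an unadjusted p under 0.05, all higher. The list of fragments of other RNAs had 6 of 10 below 0, with miR-1290 at 0 and the rest above (camera adjusted p = 0.675). Adjusted over the list alone 1 rose, miR-3648 (0.50), and 1 fell, miR-4284 (-0.63), and miR-663a gave 0.35. The uninfected values of miR-3648 lay close to the floor, and its second probe stayed at the floor on all arrays. Before scaling, its brighter probe gave 23.6 and 27.3 on the uninfected arrays and 27.3 and 32.8 on the infected arrays.

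**Figure D3:**
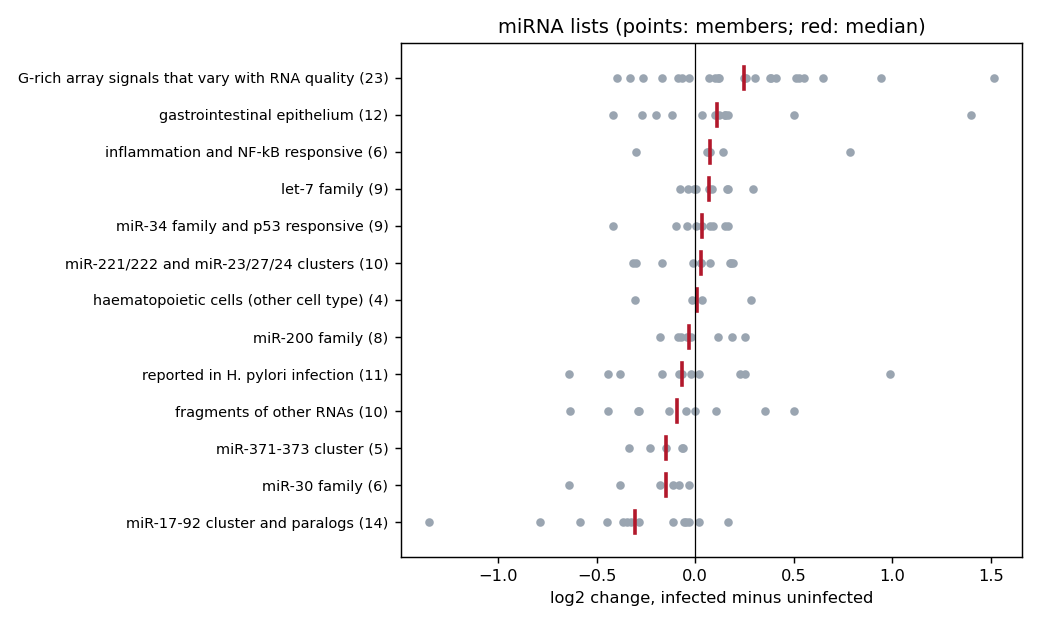
Log2 change (infected minus uninfected) of the tested members of each list with at least 3 of them (grey points, number of members in brackets) and the median of each list (red line). The miR-17-92 list has the lowest median (-0.30) and the G-rich list the highest (0.25); the medians from the miR-200 family (-0.03) up to gastrointestinal epithelium (0.11), and that of the fragments (-0.09), changed sign under another scaling or with 1 array left out.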

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

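The tests of this part were chosen after the results were seen. The arrays carry probes for viral miRNAs, for which the labels name no source in these cells, and 2 of them were not well above background on the uninfected arrays but were on both infected arrays. hcmv-miR-US33-3p was at least 5.26-fold higher in infected cells (log2 change 2.39, SE 0.40, limma adjusted p = 0.0955, higher in 2 of 2 arrays), with a mean intensity before scaling of -0.75 in uninfected and 118 in infected cells. hcmv-miR-US4 was at least 1.23-fold higher (limma adjusted p = 0.184, higher in 2 of 2 arrays). Of the 18 viral miRNAs tested, 14 were above 0 with a median of 0.29 against 0.03 for human ones. In the main setting 8 had an unadjusted limma p under 0.05 on the higher side and 0 passed. Of the 18, hcmv-miR-US33-3p and hcmv-miR-US4 entered the test through the infected arrays alone, which favours a change above 0. These 2 count in the 14, in the median, in the 8 and in the camera test of the viral set. hcmv-miR-US33-3p and hcmv-miR-US4 passed with the total signal per miRNA, the deposited table and a floor 4 times lower (limma adjusted p = 4.69e-05 to 0.00746). Neither passed in the other alternatives that kept all arrays. Some other viral miRNAs, such as ebv-miR-BART16 with the replicate number as a block, passed too. Camera gave the viral set p = 0.00978 with the preset and p = 0.137 with an estimated correlation.

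In the main setting the pattern of strong gains, log2 changes of at least 2, held 3 members: miR-671-5p, miR-670 and hcmv-miR-US33-3p. Membership depends on the floor. With a floor 4 times lower, miR-3121-3p (3.70), miR-3131 (3.08), miR-2117 (2.73), miR-4251 (2.25) and miR-658 (2.20) also reached 2. The checks below cover only the 3 members of the main setting. Array brightness and scaling are argued against, since no 2 arrays differed in brightness by more than 1.41-fold over 3 measures of it. A faulty probe or faulty spots are argued against as well, since 5 of the 5 probes of these miRNAs other than the one chosen for its brightness were over 2 times brighter on both infected arrays than on either uninfected array. Binding of RNA other than the named miRNA, such as bacterial RNA carried along with the cells, may contribute: 1.59% of the viral miRNAs undetected in uninfected cells gained detection on both infected arrays (2 miRNAs, exact 95% interval 0.193% to 5.62%), against 2.14% of human ones (20 of 936, Fisher's exact two-sided p = 1), which are too few gains to decide, and probe sequences were not compared with the bacterial genome here. A change of miR-671-5p and miR-670 in the infected cells, the group difference of the design, stays open and untested. Slide position stays open for all 3 members. The labels name no source of hcmv-miR-US33-3p, so the rise of its 4 probes is not read as a change of that viral miRNA. What bound those probes was not tested.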

How the results depend on the processing

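The 4 calls stood in most alternatives: miR-671-5p passed in 12 of 16 that tested it (log2 change 2.69 to 5.11), miR-670 in 11 of 14 (0.93 to 6.16), miR-4257 in 12 of 17 (0.53 to 1.43) and miR-93-5p in 12 of 17 (-1.57 to -1.11). The background correction by normexp with an offset of 50 on median spot signals and the test of human miRNAs alone (3 higher, 1 lower) were chosen after seeing the data. Normexp on mean spot signals was not run, since the files used here give medians, nor was the slide as a block, since 1 slide held all arrays. Against 3 higher and 1 lower, the counts were 8 and 3 with the percentile over all probes, 3 and 2 with quantile normalization, 1 and 1 with normexp, 22 and 3 with the total signal per miRNA, 21 and 5 with the deposited table, 6 and 1 with the mean of all probes (0 of the lower ones shared), 31 and 3 with a floor 4 times lower, and 7 and 1 with a trend in eBayes; the cause was not tested. Fewer or more miRNAs entered with a filter on all 4 arrays (22 higher and 6 lower of 254, without miR-671-5p and miR-670) and with no filter (0 and 0 of 1347, most at the floor, with 37 and 11 at an unadjusted limma p under 0.05). Leaving out 1 array gave 0 to 13 higher and 0 to 2 lower, with 18 to 29 and 6 to 12 at an unadjusted limma p under 0.05; the lone array of a group is then assumed to vary like the other group. The list count of 1 became 0 with quantile normalization and 7 with no filter. In the other alternatives the miR-17-92 list passed with the preset correlation. With an estimated correlation it passed in none (camera adjusted p = 0.234 to 0.999, not computed with the block), but that version has few degrees of freedom, so this decides little. With no filter its median was 0. The difference in detected miRNAs, 27.5, was 24.5 by the scanner's own flag. Within-group correlations exceeded those between groups by 0.019 on average, by 0.00960 over all human miRNAs and by 0.012 over those detected on all arrays; the cause was not tested. Signal over background limits dim miRNAs: the mean signal of negative controls was 2.87 to 3.49, and a fold from the floor is set by that floor.

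The groups share replicate numbers, but with 2 pairs and no label of a shared culture or day the numbers are not known to pair the samples. Equally numbered arrays also share the first index of their slide position, so a block by number is one by that position too. Deviations of equally numbered arrays correlated at 0.671 across miRNAs, and with the replicate number as a block 16 miRNAs were higher and 1 lower. The higher ones then included miR-1180, miR-3131 and miR-2117 (limma adjusted p = 0.0303, 0.0471 and 0.0471), and the lower one was miR-93-5p.

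Of the 1037 values of named miRNAs and lists under alternatives, 888 kept sign and side of the threshold, 68 newly passed, 18 no longer passed, and 63 that passed in neither setting changed sign. Where a scaling moved the median of all miRNAs, that shift is part of the change of sign; otherwise the cause was not tested. With the percentile over all probes, medians turned to -0.15 (inflammation), -0.15 (let-7), -0.17 (clusters of miR-221 and miR-23), -0.18 (miR-34 and p53), -0.21 (haematopoietic) and -0.11 (gastrointestinal), and changes to -0.079 (miR-21-3p), -0.057 (miR-98-5p), -0.053 (let-7g-5p), -0.033 (miR-200a-5p), -0.13 (miR-103a-3p), -0.18 (miR-142-3p) and -0.16 (miR-21-5p). In the deposited table the same medians turned to -0.13, -0.14, -0.14, -0.19, -0.15 and -0.12, and changes to -0.033 (miR-21-3p), -0.038 (miR-98-5p), -0.074 (let-7g-5p), -0.038 (miR-200b-5p), -0.16 (miR-103a-3p), -0.13 (miR-142-3p) and -0.15 (miR-21-5p). With median scaling the first 5 medians turned to -0.0064, -0.0098, -0.031, -0.043 and -0.071, miR-142-3p to -0.045 and miR-21-5p to -0.021. Quantile normalization turned the inflammation median to -8.0e-05, that of the miR-221 and miR-23 clusters to -0.049, miR-34 to -0.16 and haematopoietic to -0.073, with miR-371a-3p at 0.098, miR-200a-5p at -0.019 and miR-142-3p at -0.16. The mean of probes gave -0.046 (miR-221 and miR-23 clusters), -0.062 (miR-34), -0.079 (miR-103a-3p) and -0.00042 (miR-21-5p), and normexp 0.022 (miR-34a-3p). With 1 array left out, ranges that crossed 0 were -0.078 to 0.20 (let-7), -0.041 to 0.13 (miR-200), -0.041 to 0.032 (miR-221 and miR-23 clusters), -0.050 to 0.095 (miR-34), -0.093 to 0.14 (haematopoietic), -0.35 to 0.084 (fragments), -0.096 to 0.43 (let-7g-5p), -0.65 to 0.044 (miR-181a-3p), -0.048 to 0.12 (miR-142-3p), -0.20 to 0.075 (miR-372) and -0.11 to 0.20 (miR-21-5p).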

Other observations

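Of the tests below, those of the list without miR-93-5p and of lists matched on signal were set before their results were seen, and the others after. More miRNAs were detected on the infected arrays: 20 human miRNAs were well above background on both infected arrays and on neither uninfected array, and 2 went the other way, miR-30b-3p and miR-3176. Beyond miR-670, the human miRNAs with the larger bounds, chosen after their values were seen, were miR-3121-3p at least 3.25-fold (limma adjusted p = 0.103), miR-3131 at least 2.11-fold and miR-4313 at least 1.77-fold (limma adjusted p = 0.0658 for the last). The floor sets these bounds, so they do not rank the gains. Before scaling, miR-4313 had a mean intensity of 21.2 in uninfected and 36.8 in infected cells, against -0.97 and 34.2 for miR-2117. Only miR-670 of these 22 passed the adjusted threshold, and 14 of the 20 gains were under 1.5-fold as bounds.

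The fall of miR-93-5p stood apart from its cluster. Relative to the mean of miR-106b-5p and miR-25-3p on the same array, it went from -0.40 ± 0.04 in uninfected to -1.75 ± 0.10 in infected cells (SD, n = 2), a change of -1.34 (SE 0.07) that no scaling factor of an array can alter. A lower yield of the shared precursor transcript would lower all 3 alike only if the mature miRNAs turn over alike. Precursor and turnover were not measured, so a lower yield is argued against as the whole of the fall only under that condition. A single bad probe is argued against too, since the smaller fall of its probes was -0.94. The group difference of the design and slide position stay open and untested.

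The lower level of the miR-17-92 list may extend beyond miR-93-5p. Without that member, camera gave p = 0.000308 (p = 0.0612 with an estimated correlation) and the median was -0.28. The median and the preset test argue against miR-93-5p alone. The version with an estimated correlation, with few degrees of freedom, does not decide. Bright probes drifting downward are argued against, since 0% of 10000 random human lists matched on mean signal had a median as low (central 95% from -0.11 to 0.15), although random lists do not carry the shared signal of related sequences. Scaling stays open. The median relative to all tested miRNAs was -0.34, and -0.38 to -0.35 with the other percentile, the median and the deposited table. The other percentile and the median divide each array by 1 factor, so they could hardly move this relative median. Quantile normalization, which is not 1 factor per array, reduced it to -0.20 and ended the call. Changes other than scaling reduced it too, to -0.22 with the mean of all probes, -0.25 with normexp and -0.22 without infected replicate 1. Cross-binding among these similar sequences and a coordinated fall in infected cells both stay open and untested.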
